A study of Mus musculus with 4 samples.

How the data were processed

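RNA of cells sorted by flow cytometry from the submandibular gland of C57BL/6 mice aged 8 to 10 weeks was measured on 4 one-colour Agilent arrays, 2 of stem cells and 2 of non-stem cell epithelia, per the labels. The markers used for the sort are not given in the sources used here. Total RNA was purified on columns with a DNase step, amplified and labelled with Cy3, per the labels' protocols. The deposited scanner files hold spot intensity on a linear scale, and per the file headers they were made with Agilent Feature Extraction 10.7.3.1 on a mouse design with coordinates on mm9 (NCBI build 37). The submitters' processing notes name Feature Extraction 9.1 instead, and this difference was not resolved. The background-corrected signal that Feature Extraction writes was the starting value.

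The deposited series table holds log2 values made by the authors, with no scale or centring stated. Differences between arrays in that table correlated at 1 with those of the scanner values after the 75th percentile shift, so its scale is log2 and its direction is settled. Each probe was centred on a baseline that stays unknown. The column medians were -0.28 and -0.55 for stem cells replicates 1 and 2, and -0.83 and -0.76 for non-stem cell epithelia replicates 1 and 2.

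Each array held 59305 non-control spots of 55681 probes. Control spots and spots flagged as outliers were left out, log2 signals were shifted by the array's 75th percentile over non-control probes, and spots of a probe were averaged. A probe was tested where it was well above background on at least 2 of the 4 arrays. A gene was represented by its brightest tested probe. Of the 3919 genes with several tested probes, 1315 had probes of opposite sign, and among the 1148 of them past the threshold 211 had one. Names came from the RefSeq gene table of assembly GRCm38.p6 through unversioned accessions, which named 26582 probes, and the other 29099 kept the array's name. Coordinates are those of the probes in the scanner files.

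Stem cells were compared with non-stem cell epithelia by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 5.53 degrees of freedom in all, and the number of arrays limits the precision of each value. Nothing in the labels says that the replicates came from separate animals or sorts, so the p-values measure only the spread between these samples, which may be technical. Where a probe was well above background on neither array of a group, the fold is a bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background. The p-value of such a gene comes from the signals without this limit, so it does not test the bound.

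Before the data were examined, 29 lists of genes were fixed, 12 of cell type markers and 17 of pathways and other groups. They hold 680 distinct genes, of which 36 stand in more than 1 list. The 26 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The latter rests on the residuals of only 4 arrays, so it had little power. Its smallest unadjusted p over the lists was 0.018 by camera, for cell cycle genes. A list that did not pass it is therefore left undecided by that test. Genes named in the text were chosen by a rule also fixed in advance. It takes the 12 largest rises and 12 largest falls among genes past the threshold, measured on all 4 arrays and without overlap between groups. It adds the 5 largest bounds each way, up to 4 genes of smallest p from each list, and 14 genes fixed by name. RIKEN, model and accession-like names were left out. Genes named beyond that rule were chosen after their values were seen.

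The fit was tested on simulated data for this comparison after it had first been run on the arrays, and was not altered afterwards. The simulation had 17362 genes with the real mean levels, spreads drawn from the fitted prior and 200 genes changed. It recovered 0 of 50 genes changed by 0.5 on the log2 scale, 4 of 50 changed by 1, 37 of 50 changed by 2 and 48 of 50 changed by 4. Of its 95 calls, 6 were unchanged genes, or 6.32%. The real comparison had 5373 calls, which makes its cutoff on the unadjusted p less strict. The recovered shares therefore do not give its power. In a separate simulation of 26 lists of 25 genes, camera found the 1 list that was moved and called 0 of the others. Its genes were drawn independently, so it cannot show how camera treats lists of correlated genes.

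The alternatives were quantile normalization, normexp background correction with an offset of 50, the deposited log2 values, no filter, a filter on all 4 arrays, an intensity trend with robust variances, the replicate number as a block, the mean of a gene's probes, an estimated correlation, a 2-fold minimum and leaving out each array. A 75th percentile over the probes detected on all arrays, and a crossed pairing of the replicates, were added after seeing the data. All 4 arrays lay on 1 slide with 1 scan time, so no batch could be tested. Figures were drawn with matplotlib 3.10.9.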

Results

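Gene expression was measured in stem cells and non-stem cell epithelia sorted from the mouse submandibular gland, with 2 arrays per group. The comparison asks which genes distinguish the stem cells of this salivary gland from its other epithelial cells. The 75th percentile of the signal was 34.0 and 48.9 on the stem cell arrays and 84.2 and 71.1 on the non-stem arrays. The share of spots well above background was 35.7% and 39.0% in stem cells and 42.3% and 41.9% in non-stem cell epithelia, and no spot was saturated. Arrays of one group correlated across genes at 0.986 in stem cells and 0.992 in non-stem cell epithelia, and arrays of different groups at 0.923 to 0.935.

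Stem cells carried higher levels of Krt14, Wnt10a and Mki67 and lower levels of Bpifa2 and Aqp5. Krt14, a keratin of basal epithelial cells, was 8.96-fold higher, with a log2 change of 3.16 ± 0.16 (SE, n = 2 arrays per group). Wnt10a, a secreted Wnt ligand, was 27.4-fold higher (log2 4.78 ± 0.30) and Mki67, a marker of cycling cells, 5.46-fold higher (2.45 ± 0.16). Bpifa2, the salivary protein also known as parotid secretory protein, fell by 4.55 ± 0.19 on the log2 scale, and Aqp5, the water channel of acinar cells, fell by 3.19 ± 0.16. Of 17362 genes and transcripts tested, 2454 were higher and 2919 lower in stem cells by limma, 1226 and 1667 of them by at least 2-fold.

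**Figure D1:**
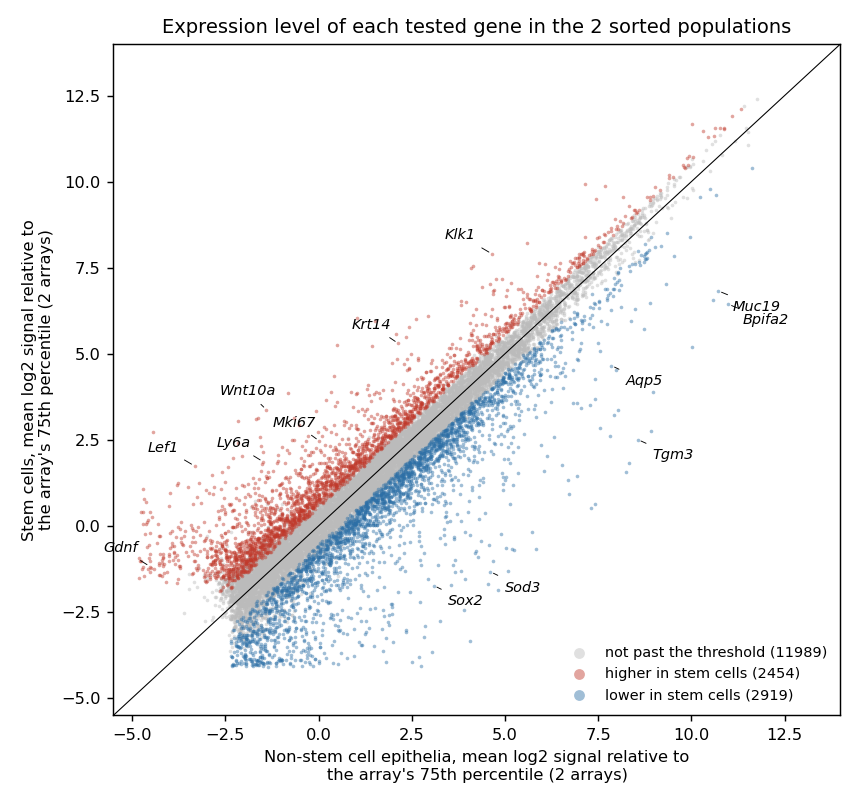
Mean log2 signal relative to the array's 75th percentile of each tested gene in non-stem cell epithelia (horizontal) and stem cells (vertical), 2 arrays each. Red points (2454) were higher and blue points (2919) lower in stem cells at an adjusted p under 0.05, and the line marks equal levels.

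Among genes measured on all 4 arrays, the largest rise was that of Rgs7bp, which encodes a protein that binds regulators of G protein signalling, at 4.98 ± 0.33 (SE) on the log2 scale, or 31.6-fold. Its probe lies on chromosome 13 at 105737233 to 105737258 (mm9). It was followed by Wnt10a on chromosome 1 at 74850633 to 74850692, the chemokine gene Cxcl10 (4.77 ± 0.16), Smoc2 (4.76 ± 0.17), the growth factor gene Ptn (4.75 ± 0.18), Ucma, Megf6, Ly6d (4.44 ± 0.16), Ndrg1, Amy1, Pdpn and Slc12a4. The largest fall was that of Igsf9b, on chromosome 9 at 27137619 to 27137678, which fell by 6.78 ± 0.39. Cd300lg fell by 6.49 ± 0.34, Ppp1r14c by 6.15 ± 0.31, and the transglutaminase gene Tgm3 fell by 6.05 ± 0.34. Sod3, the extracellular superoxide dismutase, fell by 5.93 ± 0.17. B3gnt6, Cgref1, Lman1l and the major urinary protein genes Mup6, Mup19, Mup9 and Mup20 were also among the 12 largest falls. The Mup genes are near-identical copies, so their probes may share transcripts and their separate values are uncertain. Of genes not well above background in non-stem cell epithelia, Lef1, a transcription factor of the Wnt pathway, was at least 19.1-fold higher in stem cells, Fgfr3 at least 16.6-fold, Bcat1 at least 16.0-fold, Il18r1 at least 13.5-fold and Pcdh19 at least 13.4-fold. These bounds hold for the brightest probe, and the lowest log2 change among the tested probes was 2.97 for Lef1 and 3.12 for Bcat1. Of genes not well above background in stem cells, Prkcb was at least 40.1-fold lower there, Mrgprb1 at least 28.1-fold, Tbx1 at least 26.1-fold and Kcnk6 at least 24.7-fold, with Ceacam10 between them. The bound of Mrgprb1 depends on 1 array, since its log2 signal in non-stem cell epithelia was 1.49 and 3.55.

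Of 19 tested markers of basal duct and myoepithelial cells, 11 rose and 1 fell, or 12 and 1 adjusted over the list alone. Krt17 rose by 3.79 ± 0.16, the cadherin gene Cdh3 by 3.22 ± 0.17 and Krt5 by 3.15 ± 0.20. The list as a whole was higher by camera (adjusted p = 3.6e-05), but not past the threshold with an estimated correlation (adjusted p = 0.22). Of 27 tested markers used for salivary stem and progenitor cells, 8 rose and 7 fell, or 9 and 7 adjusted over the list alone, and the list did not pass the test (adjusted p = 0.34). Ly6a, which encodes the stem cell antigen Sca-1, rose by 3.35 ± 0.33 and the neurotrophin receptor gene Ngfr by 3.62 ± 0.18. Kit, a receptor used to sort salivary progenitors, rose by 0.84 ± 0.15, and Cd24a fell by 1.05 ± 0.15. The sort markers are not given, and the change of a gene used for the sort is no finding. The calls of Kit and Cd24a were lost without non-stem replicate 1 (adjusted p = 0.084 for Kit and 0.052 for Cd24a) and without non-stem replicate 2 (0.080 and 0.063). The integrin gene Itga6 had a log2 difference of 0.39 ± 0.18 (adjusted p = 0.15). Sox2, a transcription factor of progenitor cells, fell by 4.82 ± 0.15, though it was above background on only 1 stem cell array. The list has 18 of its 28 genes in common with other lists.

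Gdnf, which encodes a neurotrophic factor, was above background on both stem cell arrays and on neither non-stem array, and was at least 2.52-fold higher in stem cells. Its limma adjusted p = 0.00072 does not test that bound. It belongs to a log2 change of 3.34, which rests on non-stem signals that were not well above background. Artn, of the same family, was at least 2.80-fold higher. Their common receptor gene Ret had a log2 difference of 0.34 ± 0.21 (adjusted p = 0.26), and the co-receptor gene Gfra1 was not well above background on any array. Gfra3, the co-receptor gene for Artn, rose by 1.07 ± 0.16. Among 16 tested genes of the GDNF family, the neurotrophins and their receptors, 7 rose and 2 fell, the same counts as adjusted over the list alone. Ntrk2, a neurotrophin receptor, fell by 4.99 ± 0.22. The list passed camera (adjusted p = 0.0095), but not with an estimated correlation (adjusted p = 0.28).

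**Figure D2:**
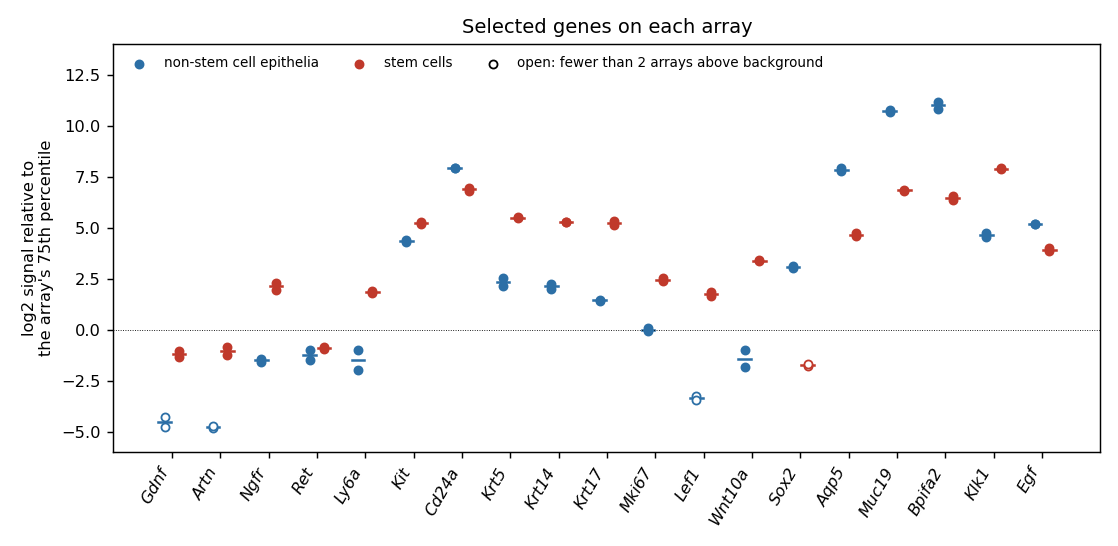
Log2 signal relative to the array's 75th percentile for selected genes on each array. Points are arrays, short lines are means of 2 arrays, and open points mark groups in which fewer than 2 arrays were above background, as for Gdnf and Artn in non-stem cell epithelia.

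Among 22 tested markers of acinar secretory cells, 12 fell and 1 rose, the same counts as adjusted over the list alone. The mucin gene Muc19 fell by 3.89 ± 0.16, Cldn10 by 3.72 ± 0.15 and the transcription factor gene Etv1 by 3.61 ± 0.16. The exception was the amylase gene Amy1, which rose by 4.08 ± 0.20 and belongs to a family of similar copies. The other 9 did not pass. Of these, Prol1 had a mean log2 signal of 8.80 in stem cells and 8.78 in non-stem cell epithelia, and Dcpp3 11.45 and 11.52. Car6 stood at 9.75 and 10.05. The list was lower by camera (adjusted p = 2.6e-05), but not past the threshold with an estimated correlation (adjusted p = 0.22). Of 20 tested markers of granular convoluted tubule cells, the androgen-dependent secretory duct cells of the mouse gland, 15 rose and 1 fell, with the same counts adjusted over the list alone. Most of them are kallikreins, a family of closely related proteases. Klk1 rose by 3.25 ± 0.16, Klk1b5 by 2.78 ± 0.15, Klk1b3 by 2.61 ± 0.16 and Klk1b24 by 2.43 ± 0.15. The copies have similar transcripts, so their separate values are uncertain. The Klk1b24 probe matched other kallikrein probes over only 4 of 60 bases, but its match to their whole transcripts was not tested. Of other products of these cells, Crisp3 rose by 1.54 ± 0.16 and Egf fell by 1.26 ± 0.16. The list passed camera (adjusted p = 1.4e-06), but not with an estimated correlation (adjusted p = 0.22). Of 21 tested markers of the other ducts, 11 rose and 1 fell over all genes and over the list alone. Cldn4 rose by 2.51 ± 0.21, Wfdc2 by 1.97 ± 0.17, Fxyd2 by 1.73 ± 0.15 and Clu by 1.66 ± 0.15 (list adjusted p = 0.00015, and adjusted p = 0.22 with an estimated correlation).

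Of 24 tested cell cycle genes, 20 rose and none fell, and 22 rose adjusted over the list alone. The cyclin gene Ccnd2 rose by 2.95 ± 0.25, Birc5 by 2.23 ± 0.17 and the replication gene Mcm3 by 1.83 ± 0.16. This list had the smallest p by camera (adjusted p = 1.4e-09), and an adjusted p = 0.22 with an estimated correlation. Among 33 tested Wnt pathway genes, 13 rose and 6 fell, or 14 and 6 adjusted over the list alone. Wnt10b was at least 5.14-fold higher and Rspo1, which encodes an enhancer of Wnt signalling, at least 2.41-fold. The list passed camera (adjusted p = 0.035), but not with an estimated correlation (adjusted p = 0.29) or with the percentile over detected probes (adjusted p = 0.087). Of 20 TGF-beta and BMP pathway genes 9 rose and 2 fell over all genes and over the list alone. Bmp7 rose by 2.92 ± 0.16, Id3 by 2.73 ± 0.17 and Tgfb2 by 2.21 ± 0.19, while Id4 fell by 3.59 ± 0.25 (list adjusted p = 0.0048, and adjusted p = 0.29 with an estimated correlation). Of 29 integrin, laminin and basement membrane genes, 15 rose and 3 fell, or 16 and 4 adjusted over the list alone. Nid1 was at least 6.14-fold higher, Lamb3 rose by 2.37 ± 0.17 and Lamb1 by 2.29 ± 0.17 (list adjusted p = 0.00049, and adjusted p = 0.29 with an estimated correlation).

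Among 18 tested chemokines, cytokines and inflammation genes, 13 rose and 2 fell, or 15 and 3 adjusted over the list alone. Vcam1, an adhesion molecule, was at least 9.74-fold higher, Cxcl12 at least 4.66-fold, and Tnfaip3 rose by 2.64 ± 0.17, while Ccl28 fell by 3.40 ± 0.18 (list adjusted p = 3.7e-05, and adjusted p = 0.22 with an estimated correlation). Of 20 immediate early genes, 11 rose and 3 fell, or 15 and 3 adjusted over the list alone. Egr2 rose by 2.81 ± 0.15, Fosb by 2.20 ± 0.16 and Klf6 by 2.16 ± 0.18 (list adjusted p = 0.00015, and adjusted p = 0.28 with an estimated correlation). Among 25 heat shock and unfolded protein response genes, 13 fell and 5 rose, or 13 and 6 adjusted over the list alone. Sdf2l1 fell by 2.59 ± 0.17, Manf by 2.27 ± 0.15 and Xbp1, a transcription factor of the unfolded protein response, by 2.19 ± 0.16. The list passed camera (adjusted p = 0.040), but not with an estimated correlation (adjusted p = 0.58) or with quantile normalization (adjusted p = 0.053). Of 17 cell cycle inhibitors and p53 targets, 7 rose and 2 fell, or 8 and 2 adjusted over the list alone, with Gadd45b up by 2.68 ± 0.15 (list adjusted p = 0.0093, and adjusted p = 0.41 with an estimated correlation). With normexp its median went from 0.41 to 0.05 and the call was lost (adjusted p = 0.15). Of 6 tested genes of epithelial to mesenchymal transition, 3 rose over all genes and over the list alone. Tgfbi was at least 4.77-fold higher and Snai2 rose by 2.02 ± 0.23 (list adjusted p = 0.014, and adjusted p = 0.41 with an estimated correlation).

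**Figure D3:**
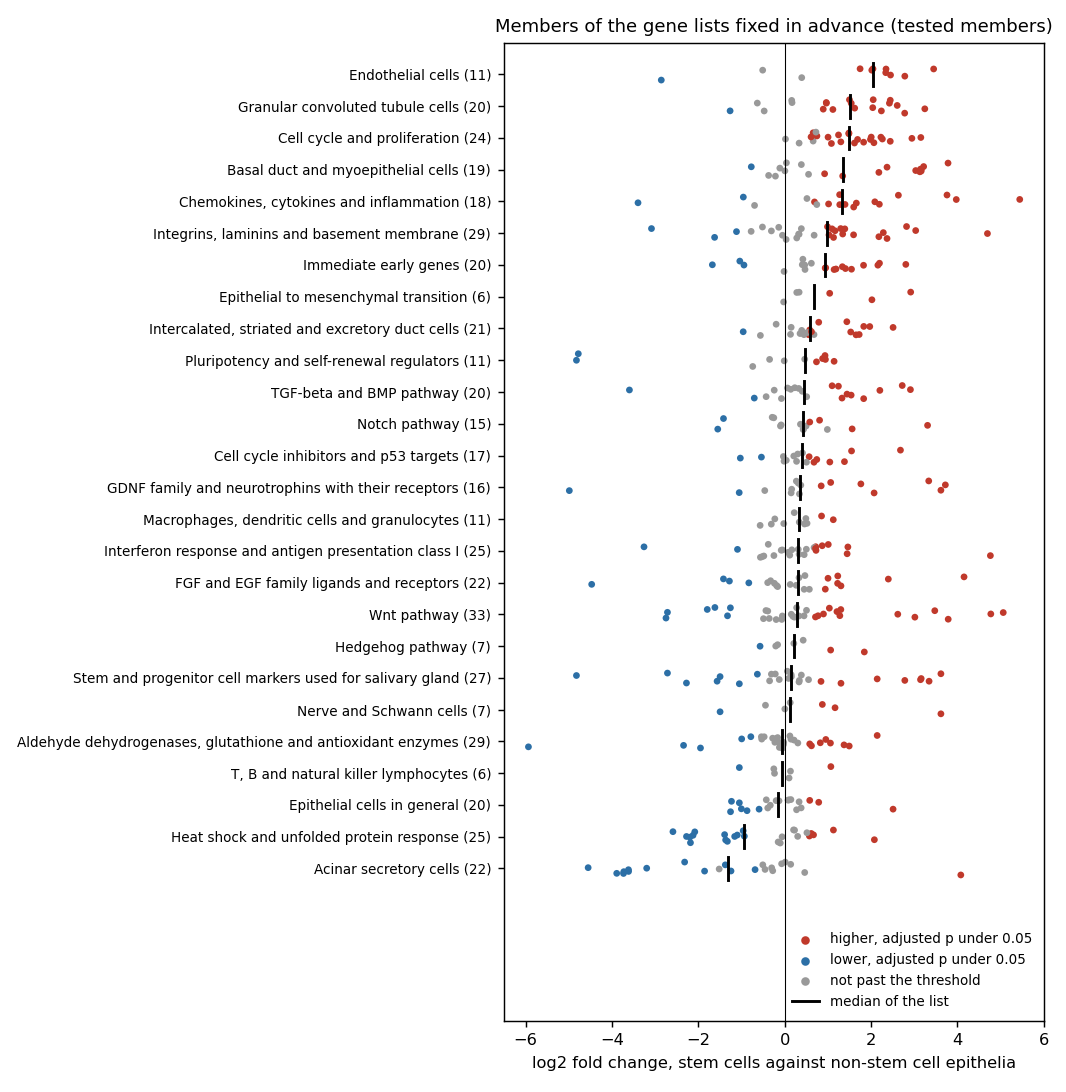
Log2 fold change of each tested member of the 26 lists tested, stem cells against non-stem cell epithelia, with the number of tested members in brackets. Points are genes, coloured by call, and the black line is the median, which ran from -1.31 for acinar markers to 2.05 for endothelial markers.

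Of 11 tested endothelial markers, 8 rose and 1 fell over all genes and over the list alone. Ly6c1 rose by 3.45 ± 0.17 and Robo4, above background on 1 non-stem array, by 2.35 ± 0.20, while Cd34 was at least 3.34-fold and Ramp2 at least 3.46-fold higher. Pecam1, a marker of all endothelial cells, had a log2 difference of -0.51 ± 0.40 (adjusted p = 0.37) and was above background on 1 stem cell array. Without stem cells replicate 1 the log2 difference of Pecam1 was -1.12. The stem cell value left, -2.93, equals the lowest signal above background on that array. The list passed camera (adjusted p = 0.00075), but not with an estimated correlation (adjusted p = 0.23). Its median was 2.05, and 0.72 with normexp. The erythroid markers Hba-a1, Hbb-b2, Alas2 and Slc4a1 were lower in stem cells, 4 of 4 tested, with Hba-a1 down by a log2 change of -2.19 ± 0.18. Ptprc, found on all white blood cells, and the fibroblast collagen gene Col1a1 were not well above background on any array, whereas the matrix gene Dcn rose by 2.14 ± 0.16, the 1 of 4 tested fibroblast markers that passed. Among mast cell markers, 1 of 3 tested rose and 2 fell, with Mrgprb1 as above.

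The other lists did not pass camera. In lymphocyte markers 1 of 6 rose and 1 fell (adjusted p = 0.83), in macrophage and granulocyte markers 2 of 11 rose (adjusted p = 0.19), and in nerve and Schwann cell markers 3 of 7 rose and 1 fell, or 3 and 2 adjusted over the list alone (adjusted p = 0.34). In general epithelial markers 3 of 20 rose and 6 fell (adjusted p = 0.52). In Notch pathway genes 4 of 15 rose, or 5 adjusted over the list alone, and 2 fell (adjusted p = 0.19), with Jag2 at least 5.42-fold higher. In FGF and EGF family genes 7 of 22 rose, or 8 adjusted over the list alone, and 4 fell (adjusted p = 0.22), with Nrg1 at least 15.2-fold lower. In hedgehog genes 2 of 7 rose and 1 fell (adjusted p = 0.39), and in interferon genes 8 of 25 rose, or 9 adjusted over the list alone, and 2 fell (adjusted p = 0.096), with Mx1 at least 2.88-fold lower. In pluripotency regulators 5 of 11 rose and 2 fell (adjusted p = 0.67), with Lin28a down by a log2 change of -4.78 ± 0.52. Their median was 0.47 and their mean -0.51, and camera pointed up. In antioxidant enzymes 8 of 29 rose and 5 fell, or 8 and 7 adjusted over the list alone (adjusted p = 1.00), with a median of -0.05 and a mean of -0.17 while camera pointed up.

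The number of calls fell when either non-stem array was left out and rose when either stem cell array was left out. In each such fit the spread between arrays came from the other group alone, so this says little about single arrays. The split also moved with scaling, since 45.7% of calls were higher here, 25.2% with normexp background correction and 59.3% with a 75th percentile over detected probes. The median of the single genes' moves was -0.28 and 0.14.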

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

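The tests of endothelial cells and of the spike-ins were chosen only after the result was seen, and the others were set down before. The guards that left the endothelial test and the test of the brightest genes undecided were added after their values were seen, as were the counts with arrays set to one mean.

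Spike-in control spots, which the comparison does not use, stood higher against the sample signal in stem cells. Over the 7 of 10 spike-ins between the dimmest 2 and the brightest, the median log2 difference was 2.26 after the 75th percentile shift (range 1.79 to 2.46, with 0.72, 2.71 and 1.24 for the 3 left out), and 7 of 7 were higher on both stem cell arrays than on both others. Before the shift the median over the same 7 was 1.34, so their signal was itself higher in stem cells. Spike-ins are added in fixed amounts, so less sample RNA labelled or hybridised per spike-in may account for the difference. So may a lower messenger RNA content per unit of total RNA, and these arrays do not separate the 2. Of the 2454 higher genes, 278 had a change above 2.26, so a scale set on the spike-ins would leave those above 0. Whether the lower signal makes genes appear lower cannot be told apart from the scaling. Lower calls were 56.6% of calls among the brightest genes and 49.9% among the dimmest, but 48.7% and 56.5% with quantile normalization, 91.9% and 20.4% with normexp, and 39.6% and 39.8% with the percentile over detected probes. A trend with probe GC content is argued against as the source of the calls, of which 95.4% stayed after it was removed. The excess of lower calls did not stay: 2980 genes were then higher and 2777 lower, and 2786 and 2615 with the arrays only set to one mean. Without the filter on dim probes the median log2 change over 36280 genes was 0.43, against -0.01 over the 17362 tested. Dim probes thus tended to lie higher in stem cells after the 75th percentile shift. Changes of genes near background may hold such an offset, and its part in the lists was not tested.

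All 14 tested Klk1 and Klk1b kallikreins were higher in stem cells, by log2 0.90 to 3.25. Carry-over of tubule cells or their RNA is left open here: of other products of these cells, Crisp3 rose by 1.54 and Egf fell by 1.26. A difference in the sex of the mice is argued against by the Y-linked genes Ddx3y and Eif2s3y, above background on all 4 arrays, and by Xist, above background on none. The median change of these Y-linked genes and Uty, which was above background on 1 array, was -0.058. Hybridisation of 1 transcript to several probes stays open. The median best match between kallikrein probes was 44.5 of 60 bases, and 9 of 14 had a match of at least 40. The other 5, with matches of 2 to 32 bases, rose too, by 0.97 to 2.43. Probes were compared only with each other, so a low match does not exclude binding of the same transcript elsewhere along it. Matches of probes to whole transcripts were not tested. The number of separate kallikrein genes that rose may therefore be smaller than 14.

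Endothelial markers were higher in stem cells with a list median of 2.05, or 0.72 with normexp, and endothelial cells in the sort could account for it. Of 22 markers, 10 were above background on both stem cell arrays and 7 on both non-stem arrays. Those of Pecam1, Kdr, Cdh5, Eng, Tie1 and Vwf that were tested had a median change of -0.51, with Vwf down by a log2 change of -2.86. By the criterion first set down this would have counted against endothelial cells. That reading was withdrawn after the value was seen, because Pecam1 lies near the floor and Kdr and Vwf are bright in non-stem cell epithelia. A bright baseline can hide a rise, but it does not account for the fall of Vwf. The log2 signal of Vwf was 1.32 and 0.55 in stem cells, against 3.74 and 3.84 in non-stem cell epithelia. Cdh5, Eng and Tie1 were above background on too few arrays to be tested, and their absence excludes nothing this close to the floor. The sort and the endothelial cells cannot be told apart here, and 1 of the 22 markers, Cd34, is also in the stem cell list.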

How the results depend on the processing

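The 75th percentile over detected probes and the crossed pairing were chosen only after the result was seen. Over 1814 values of genes named by the rule under the alternatives, 1735 kept their direction and side of the threshold. Of the rest, 67 lost the call, 10 gained it and 2 turned. Of 363 list values, 334 kept both, 25 lost the call and 4 gained it. With normexp the general epithelial list (median -0.51, camera adjusted p = 0.019) and the FGF and EGF list (0.15 and 0.040) gained it. These totals count 142 gene values and 26 list values from the deposited log2 values. Those differ from the main values almost only by the centring of each probe, so their agreement was fixed in advance.

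Normexp gave 1600 higher and 4743 lower genes, and turned Dtx1 to 0.11 and Pmp22 to -0.058. No filter gave 841 and 765 over 36280 genes. A 2-fold minimum left 1226 and 1667 by its own construction. With an estimated correlation 0 lists passed, against 15. Leaving out 1 array, with the lone array assumed to vary like the other group, gave 688 to 2875 higher, 903 to 3564 lower and 15 to 15 lists. The cause of these shifts was not tested. The median of hedgehog genes went from 0.21 to -0.06 and that of stem cell markers from 0.15 to -0.09 under normexp, and those of lymphocyte and antioxidant lists were above 0 with detected probes (0.07 and 0.09). Medians of raised lists were smaller under normexp, as for cell cycle (1.49 to 0.63), tubule (1.52 to 0.79) and chemokine genes (1.34 to 0.60). That of heat shock genes went from -0.93 to -1.40. Without the filter the calls of the GDNF, Wnt, TGF-beta, p53 and integrin lists were lost, and with the filter on all arrays those of GDNF and Wnt.

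Among the calls lost whichever non-stem array was left out were those of Kit, Cd24a, Lck, Marveld3, Disp1, Gas1, Itgam, Pmp22, Tbx3 and Tpsb2. Those of Ltb, H2-Ab1 and Mitf were lost without replicate 1 alone, and those of Fgf18, Plk2, Cdkn1c, Sparc, Sox10 and Klf4 without replicate 2 alone. Gas1 lost its call whichever of the 4 arrays was left out. With the replicate block, 2367 genes were higher and 2965 lower, and 15 lists passed. Among genes named by the rule, only the calls of Gas1 and Tpsb2 changed. Deviations of same-numbered arrays correlated at -0.10, so no shared deviation was seen, though a pairing with a small effect could not be excluded. The crossed pairing gave 2102 and 2438. Signal over background limits what could be seen: 35.7% to 42.3% of spots were well above it.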

Other observations

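The symbol families below were formed and their tests chosen only after the result was seen. Among 192 families of genes with a common symbol root, 18 passed camera, and 0 passed with an estimated correlation (adjusted p = 0.98 for each named here).

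Genes with the root Sec, many of which encode coat and translocation proteins of the early secretory pathway, were lower in 16 of 24 tested and higher in 1 (median -1.37, adjusted p = 1.3e-05). Sec23b, a coat component, fell by 3.26 ± 0.16 (SE), Sec61b, a subunit of the translocation channel, by 1.75 ± 0.18, and Sec31a by 1.54 ± 0.15. Of 11 Galnt genes, which encode enzymes that start mucin-type glycosylation, 7 fell and 2 rose (median -1.58, adjusted p = 0.026), with Galnt12 down by a log2 change of -3.88 ± 0.17. Of 12 Alg genes, for enzymes of N-glycan assembly, 7 fell (median -0.89, adjusted p = 0.0090). Mup genes fell in 7 of 9, with the limit on similar copies (median -5.09, adjusted p = 1.3e-05). Acinar secretory markers fell with them, 12 of 22 with a list median of -1.31, and a different share of secretory cells was not tested. The medians of these families stayed below 0 under quantile normalization, normexp and the percentile over detected probes, from -5.13 to -0.75.

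Of 8 Adamts genes, which encode secreted metalloproteases, 7 rose (median 2.48, adjusted p = 0.00027). Adamts2 rose by 2.78 ± 0.16 and Adamts1 by 2.76 ± 0.20. The median was 0.68 with normexp, 2.38 with quantile normalization and 2.62 with detected probes.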
